A study of Mus musculus with 2 samples.

How the data were processed

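Single Cell 3' v3 libraries were made from dissociated cortex and corpus callosum after magnetic selection of PDGFRA- and O4-positive cells, with 1 library in each of 2 groups, WT-CNO (a pool of 2 pups) and DREADD-CNO (a pool of 3 pups). The deposited values were counts, UMI counts per gene and cell barcode, made by the authors with Cell Ranger 7.1.0 and neither normalised nor filtered beyond the calling of cells. The genome build and annotation behind the 32285 features are not given in the sources used here. The lowest barcode total was 500 UMIs in both libraries. Library totals were 78794300 and 108912581 UMIs.

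Counts were processed with Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0 and igraph 0.11.9. Barcodes with fewer than 500 genes (333 in WT-CNO and 247 in DREADD-CNO) or over 10% mitochondrial UMIs (1746 and 1606, 27.9% and 23.8%) were removed, leaving 4272 and 4986. Scrublet was run per library with an expected rate of 0.8% per 1000 barcodes. Its automatic threshold called 0 and 5 barcodes, less than the minimum of 0.5%. Barcodes at or above the score quantile of the expected share were therefore removed instead, 168 and 206 barcodes. These were 3.93% and 4.13% of the barcodes scored, against expected shares of 3.42% and 3.99%. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes without sex-linked, mitochondrial and ribosomal genes were chosen. Both libraries were clustered together without integration, with 30 components, 15 neighbours and Leiden resolution 1, which gave 30 clusters. Clusters were named from marker lists for OPCs, cycling cells, later lineage stages and other brain cell types, with at least 10 leading genes of each cluster checked. Newly formed and myelin-forming clusters were merged into 1 OL-like class after the data were seen. The ribosomal-rich and ribosomal-poor states, split at 3% of UMIs on ribosomal protein mRNAs, were also defined after the data were seen, as was the comparison of named genes with their level in microglia-like cells. Cells were called female or male from UMIs of Xist and of Ddx3y, Eif2s3y, Kdm5d and Uty.

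The filters, classes, rules for genes, gene lists and comparisons were set before the data were examined, apart from the choices named here as made later. With 1 library per group no model or test was fitted. Shares have exact Clopper-Pearson 95% intervals and their differences Newcombe intervals, CPM have exact Poisson intervals, and ratios have exact intervals from the share of both libraries' UMIs; floors for a count of 0 use 3 counts. All of these cover counting error only. UMIs were summed over the cells of a class with at least 100 cells in each library and scaled to CPM; some splits of a class by sex or state held fewer. A gene was called higher or lower when the higher library had at least 20 CPM and 100 UMIs, the ratio was at least 1.5 and its interval excluded 1. Genes present in at least 10 cells entered the clustering. Named genes were the 10 highest and 10 lowest past this rule by log2 ratio with 1 CPM added, without Gm, Rik, sex-linked and erythroid genes, together with Gria1 to Gria4, Neurod6, the sex-linked genes, and from each list the 2 most abundant members and the 2 with the largest ratios. Members of lists inside the central 95% of random lists were left unnamed to keep the text short, a narrowing of this rule made after the data were seen, and not every other gene the rule takes is given in the text. For each of the 25 fixed lists with at least 3 members at a mean of 5 CPM, the median log2 ratio was placed among 10000 random lists of the same size, matched on expression within a window of 101 genes. Cycling was described in OPC-like cells thinned to 5115 UMIs, the 10th percentile of lineage cells, as cells with at least 2 UMIs of a list.

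The rule of size was tested on simulated data in which genes were changed by a factor of 2. It recovered 100% of 99, 104 and 99 changed genes in OPC-like, COP-like and OL-like cells, and passed 0 of 7453, 6787 and 6316 unchanged genes. The simulation carried counting error only, which at these minimums is small beside a factor of 2, and no variation between pups or libraries, so it says nothing about false calls from either. Alternatives were tried for scaling (TMM factors from edgeR 4.0.16 in R 4.3.3, median-of-ratios factors, and totals without mitochondrial, ribosomal and myelin genes), for filters, clustering, doublets, depth, the mix of clusters, sex and ribosomal state. The 3 scalings moved log2 ratios by at most 0.020. Positions on chromosome 6 came from GENCODE M21 on GRCm38, to which 32235 of the 32285 gene identifiers matched.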

Results

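Single-cell RNA was measured in oligodendrocyte-lineage cells taken from the cortex and corpus callosum of C57BL/6J mouse pups at postnatal day 8. All pups had received, on the day of birth, a virus that carries hM4D(Gi), an inhibitory designer receptor (DREADD), behind a neuronal promoter in a form that only Cre recombinase switches on. All pups were then given clozapine-N-oxide (CNO), the drug that activates this receptor, by mouth 2 times daily from postnatal day 2 to postnatal day 8. In the DREADD-CNO group the pups carried 1 Cre copy at Neurod6, a gene of cortical excitatory neurons, and in the WT-CNO group they carried none. Each group was 1 library, a pool of 3 Cre-carrying pups or of 2 WT pups, so no test, p-value or standard error between groups exists. Genotype, silencing, pups and library cannot be told apart in this design. Intervals are 95% intervals of counting error only and carry nothing about variation between pups. The WT-CNO library held 78794300 UMIs in 6252 cell barcodes (median 8076 UMIs and 3047 genes), and the DREADD-CNO library held 108912581 UMIs in 6754 barcodes (median 10911 UMIs and 3665 genes). After filtering, 4104 WT-CNO cells with a median of 11885.5 UMIs and 4780 DREADD-CNO cells with a median of 17591.5 UMIs remained.

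The first question was what the bead selection for PDGFRA and O4, surface markers of oligodendrocyte precursors and of later lineage cells, had captured. Oligodendrocyte-lineage cells were 3424 of the 4104 WT-CNO cells and 3916 of the 4780 DREADD-CNO cells. Microglia-like cells were 8.11% (7.30 to 8.99) of the WT-CNO cells and 4.87% (4.28 to 5.52) of the DREADD-CNO cells, and border macrophage-like cells were 3.12% and 3.64%. Endothelial-like cells numbered 3 in the WT-CNO library (0.0731%) and 84 in the DREADD-CNO library (1.76%). Astrocyte-like cells numbered 3 and 35 (0.0731% and 0.732%), fibroblast-like cells 5 and 36 (0.122% and 0.753%), and pericyte-like cells 3 and 13 (0.0731% and 0.272%). Choroid-like cells, which secrete the thyroid hormone carrier transthyretin (Ttr), were 0 of the 4104 WT-CNO cells, which allows a share of up to 0.0731%, and 11 DREADD-CNO cells (0.230%). A pair of clusters stayed unnamed, with 4.995% and 5.816% of the cells. Of these, cluster 4 (179 and 206 cells, median 810 UMIs) was led by Rgs5 and scored best on the pericyte or smooth muscle list. Cluster 16 (26 and 72 cells) scored best on the astrocyte list. Pericyte-like and astrocyte-like cells may therefore be undercounted.

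The main question was whether silencing of cortical excitatory neurons in the first postnatal week went with another distribution of lineage cells over the stages of differentiation. Oligodendrocyte precursor (OPC)-like cells, which divide and carry Pdgfra, were 77.2% (75.8 to 78.6) of lineage cells in the WT-CNO library and 62.4% (60.8 to 63.9) in the DREADD-CNO library, a difference of -14.9 percentage points (-16.9 to -12.8). Committed precursor (COP)-like cells, which carry Gpr17 and Bcas1, were 16.2% (14.9 to 17.4) and 28.4% (27.01 to 29.9), a difference of 12.3 points (10.39 to 14.1). Oligodendrocyte (OL)-like cells, which carry the myelin genes, were 6.63% and 9.22%, a difference of 2.59 points (1.35 to 3.82). Among female cells the differences were -12.9, 11.8 and 1.09 points for OPC-like, COP-like and OL-like cells, and among male cells -16.4, 12.6 and 3.73 points. The lineage clusters fell into a ribosomal-rich state, with cluster medians of 4.97% to 11.7% of UMIs on ribosomal protein mRNAs, and a ribosomal-poor state, with 1.33% to 1.96%. Over both libraries, ribosomal-poor and ribosomal-rich cells had medians of 3205 and 6233.5 genes. Their median mitochondrial shares were 5.97% and 4.03%, and those of the nuclear RNA Malat1 4.01% and 1.58%. Whether ribosomal-poor cells are damaged cells, nuclei or a biological state was left open. Ribosomal-poor cells were 63.6% of lineage cells in the WT-CNO library and 39.1% in the DREADD-CNO library. Among OPC-like cells they were 75.2% and 51.6%, among COP-like cells 24.2% and 18.5%, and among OL-like cells 24.2% and 18.6%. Within ribosomal-rich cells the OPC-like share was 52.6% and 49.6%, a difference of -2.95 points (-6.36 to 0.479), the COP-like difference was 4.42 points (1.12 to 7.65) and the OL-like difference was -1.47 points. Within ribosomal-poor cells the OPC-like share was 91.3% and 82.2%, a difference of -9.14 points (-11.4 to -6.92), and the COP-like and OL-like differences were 7.29 and 1.85 points.

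**Figure D1:**
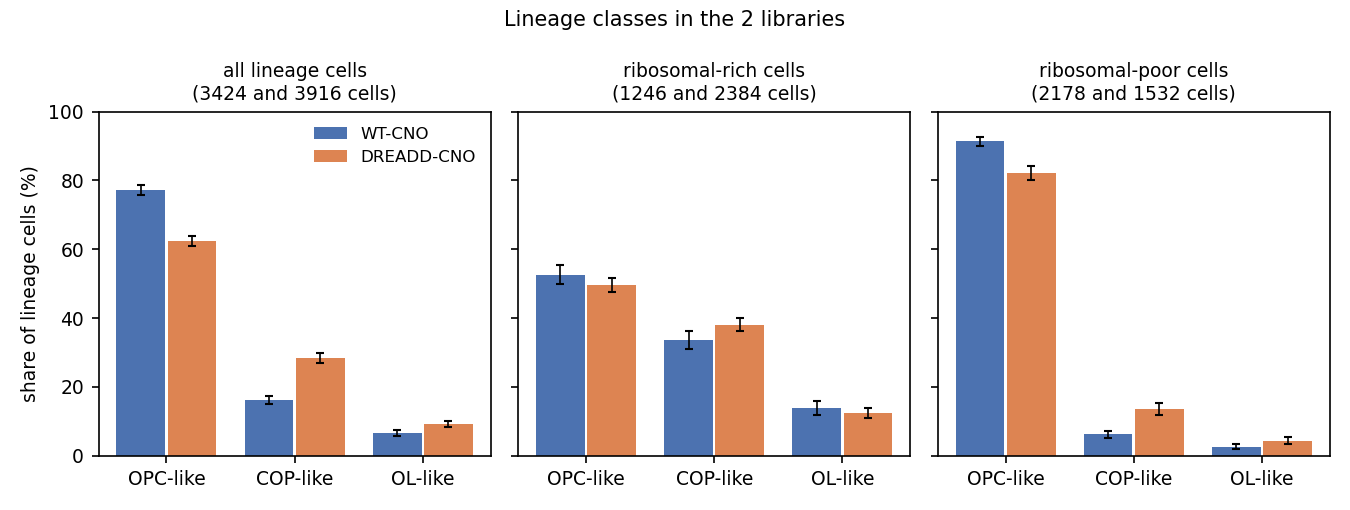
Share of lineage cells (%) in the OPC-like, COP-like and OL-like classes of each library, for all lineage cells and for ribosomal-rich and ribosomal-poor cells; bars are shares and lines are exact 95% intervals of counting error. The OPC-like share was 77.2% and 62.4% among all lineage cells, 52.6% and 49.6% among ribosomal-rich cells, and 91.3% and 82.2% among ribosomal-poor cells.

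Among OPC-like cells, clusters 5, 10 and 9 were the largest in the WT-CNO library (492, 488 and 483 cells), and clusters 0, 5 and 9 in the DREADD-CNO library (556, 384 and 314 cells). COP-like cells lay in cluster 12 (313 and 618 cells), cluster 14 (134 and 206) and cluster 23 (106 and 289). OL-like cells lay in cluster 6 (93 and 197 cells), cluster 7 (55 and 67), cluster 8 (37 and 49) and cluster 17 (42 and 48). Ribosomal-rich lineage cells had a median of 26084.5 and 25820.0 UMIs, and ribosomal-poor cells a median of 8599.5 and 8980.0 UMIs, so depth differed more between the states than between the libraries within a state. Cluster 3, placed with OPC-like cells, held Lhfpl3 of the OPC markers and 2 markers of other lists among its 10 leading genes over other classes, while clusters 0, 1, 5, 9, 10, 18 and 22 of this class held none of either kind. Cluster 9 was shallow, at 0.404 of the median depth of its library, and its best-scoring marker list was the erythroid one. The OL-like cluster 17 was shallower still, at 0.200 with a median of 2994 UMIs.

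**Figure D2:**
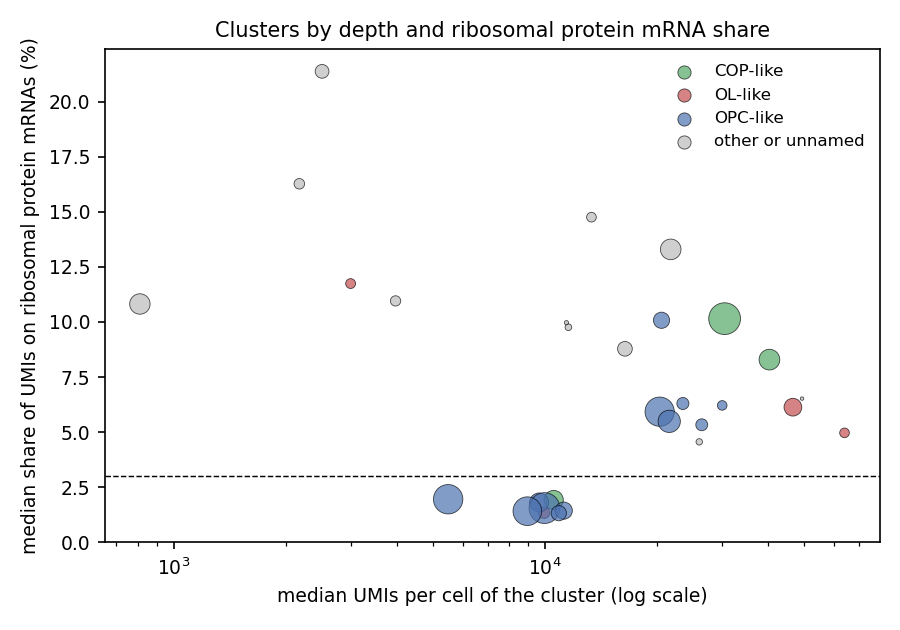
Each point is 1 of 30 clusters, placed by its median UMIs per cell (log scale) and the median share of UMIs on ribosomal protein mRNAs (%), with area proportional to its cells and colour showing its class; the dashed line marks 3%. Ribosomal-poor lineage clusters had medians of 1.33% to 1.96% and ribosomal-rich lineage clusters 4.97% to 11.7%.

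The pools differed in sex, which the labels do not give. In the WT-CNO library 76.0% of cells carried UMIs of Xist, the RNA that silences an X chromosome in females, with none of the Y-linked genes, and 10.1% carried the reverse. In the DREADD-CNO library the shares were 22.4% and 57.1%. Cells with both signals were 5.12% and 9.31%, and cells with neither were 8.70% and 11.2%. In OPC-like cells Xist was at 1439.7 CPM (UMIs scaled to the total of the class) in the WT-CNO library and 439 CPM in the DREADD-CNO library, and Tsix, its antisense RNA, at 127 and 35.9 CPM. The Y-linked genes had DREADD-CNO over WT-CNO ratios of 6.36 for Ddx3y, 5.24 for Eif2s3y, 4.51 for Kdm5d and 4.62 for Uty. Ribosomal-poor cells were 65.6% and 42.2% of female lineage cells, and 66.3% and 38.7% of male lineage cells.

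Neurod6, the gene that carries the Cre allele, had 1 UMI in WT-CNO OPC-like cells and 10 UMIs in 8 DREADD-CNO OPC-like cells, with a ratio of 8.84 (1.26 to 384). It had 0 UMIs in COP-like, OL-like and microglia-like cells of both libraries. Neurod6 belongs to neurons and no cluster was named as neurons, so its level in these cells does not report on the cells in which the receptor was switched on.

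Within OPC-like cells, 7803 genes were measured, of which 46 were higher and 22 lower in the DREADD-CNO library by the size rule. Within ribosomal-rich cells 17 were higher and 72 lower, and within ribosomal-poor cells 14 and 32, so the balance turned within each state. With mitochondrial, ribosomal and myelin genes left out of the scaling total, the numbers were 57 and 15. The activity-regulated transcription factor genes Fos and Egr1 were higher, at 15.5 and 40.4 CPM for Fos (ratio 2.61, 2.36 to 2.89) and 80.1 and 188 CPM for Egr1 (ratio 2.35, 2.25 to 2.46). Ier2, another immediate early gene, had a ratio of 1.76. The myelin gene Mbp (95.5 and 159 CPM, ratio 1.67) was higher, as were S100a4, a calcium-binding protein gene, with a ratio of 1.68, and Pcp4, a calmodulin regulator gene, with 1.66. Trnp1, a nuclear factor gene of neural progenitors, had a ratio of 1.66, and Wipi1, an autophagy gene, had 1.69. Ttr had the largest ratio, at 0.438 and 30.7 CPM (70.1, 42.3 to 126). Lower genes included Tmem117, a membrane protein gene (28.1 and 10.1 CPM, ratio 0.359, 0.319 to 0.404), and Hmga2, a chromatin gene of growing progenitors (31.9 and 14.9 CPM, ratio 0.466, 0.421 to 0.516). Tenm2, an adhesion gene, had a ratio of 0.598, the mitotic genes Cdca2, Kif23 and Ttk had 0.587, 0.630 and 0.647, and the receptor genes Ror2, Ephb2 and Gpr149 had 0.633, 0.653 and 0.639. Jpx, an activator of Xist, had a ratio of 0.651, and ratios of 0.808 in female and 0.846 in male cells, neither past the rule. Of the 10 named higher genes, 5 kept a ratio of at least 1.5 within ribosomal-rich cells and 5 with the same mix of clusters in both libraries. Of the 10 named lower genes, 7 and 4 did so. Within female cells 9 of the higher and 7 of the lower genes kept a change of at least 1.5 times, and within male cells 9 of the higher and 0 of the lower. In male cells Tmem117 had a ratio of 0.673, Hmga2 0.880, Tenm2 0.894, Kif23 0.926 and Ror2 1.02. Hmga2 in ribosomal-poor males was at 19.6 and 18.6 CPM, and in ribosomal-rich males at 10.7 and 12.1 CPM. With the same mix of clusters 12 genes were higher and 9 lower, of which 10 and 6 were among the 46 and 22. In microglia-like cells 8 of the 10 named higher genes were higher in value too, and 6 rose by at least as many CPM as in OPC-like cells. Of the 10 named lower genes 7 were lower in value there, and 0 fell by as many CPM.

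Of the 25 fixed gene lists measured in OPC-like cells, 5 had a median above and 3 a median below the central 95% of random matched lists, a description of these 2 libraries. The immediate early list, whose members respond within minutes to activity and to handling, had a median log2 ratio of 0.71 (percentile 100). Of its 9 measured members 3 were higher by the rule and none lower, and Jun had a ratio of 1.26. The myelin list, with a median of 0.47 (percentile 100), had all 10 members higher in value and 3 by the rule, among them Sirt2 (ratio 1.51), while Cd9 had 1.255. The cholesterol synthesis list had a median of 0.28 (percentile 99.98), with 21 of 21 members higher in value and 1 by the rule, Idi1 (ratio 1.54). Hmgcs1, Msmo1 and Insig1 of that list had ratios of 1.37, 1.18 and 1.39. The glycolysis list had a median of 0.30 (percentile 99.96) with 0 of 15 members past the rule, and ratios of 1.31 for Gapdh, 1.33 for Pgam1 and 1.45 for Aldoa. Targets of BMP, Notch and Wnt signalling had a median of 0.21 (percentile 98.6), with 2 of 10 members higher by the rule, and ratios of 1.14 for Hes5, 1.501 for Nrarp and 1.53 for Id3. The lower side held the G2 and M phase list, the S phase list and the NMDA and kainate receptor list, each with 0 members past the rule. All 9 NMDA and kainate receptor genes were lower in value, with a median of -0.18 (percentile 0.575) and ratios of 0.915 for Grik2, 0.880 for Grin3a, 0.771 for Grik3 and 0.791 for Grik1. This list was lower in microglia-like cells (-0.65) and border macrophage-like cells (-0.48) as well. The other 17 lists had medians between -0.13 for synaptic adhesion genes and 0.19 for cell cycle exit genes, and the OPC identity list was at 0.0058 (percentile 80.5). With the same mix of clusters, 3 of the 5 higher and 3 of the 3 lower lists stayed outside the central range on the same side. The 2 that did not were glycolysis, at 0.017, and BMP, Notch and Wnt targets, at -0.084. Within ribosomal-rich cells these were at -0.030 and -0.0036, and within ribosomal-poor cells at 0.092 and -0.13.

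**Figure D3:**
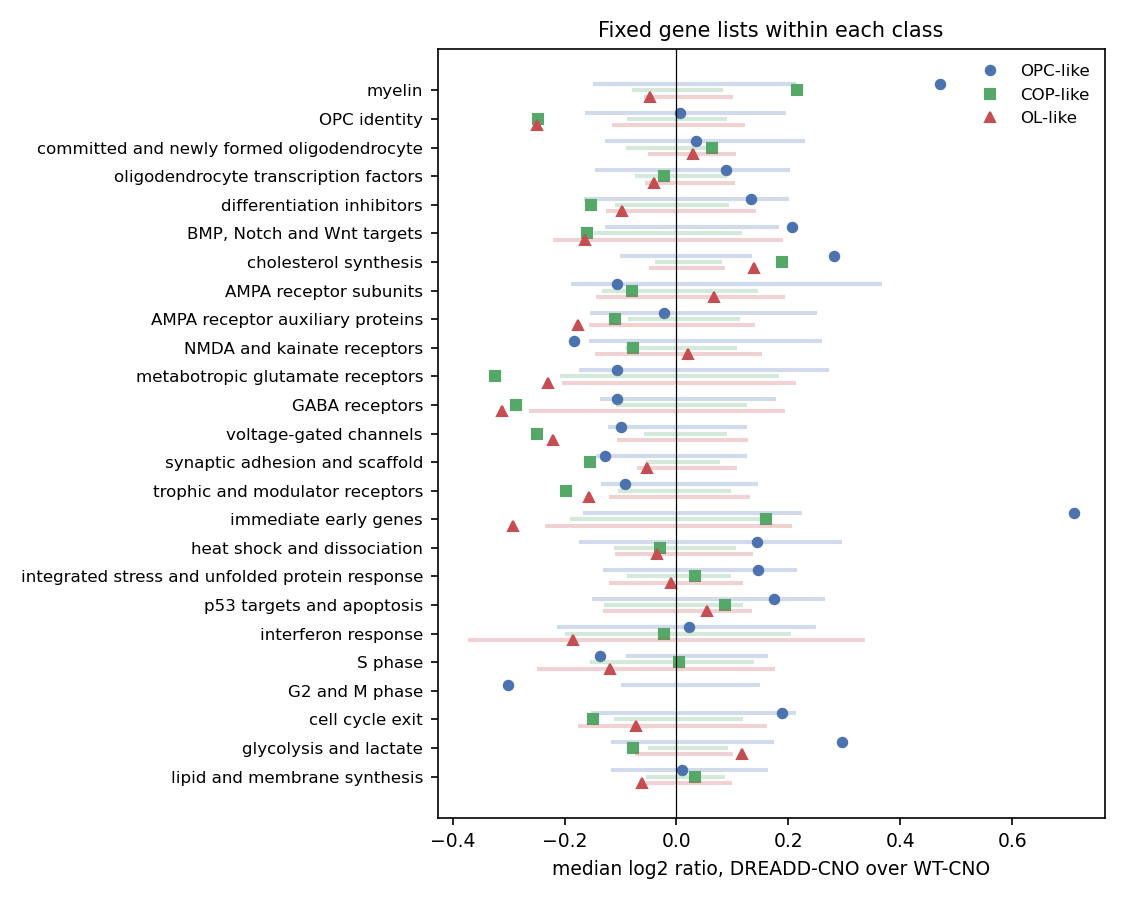
Median log2 ratio of DREADD-CNO over WT-CNO for each fixed gene list in OPC-like, COP-like and OL-like cells; points are medians and pale lines are the central 95% of 10000 random matched lists. In OPC-like cells the immediate early list lies at 0.71, the myelin list at 0.47 and the G2 and M phase list at -0.30.

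Immediate early genes were examined by state and sex, since these differed between the libraries. Egr1 in ribosomal-rich OPC-like cells was at 123 and 189 CPM in females and at 58.9 and 266 CPM in males. In ribosomal-poor OPC-like cells it was at 55.3 and 71.8 CPM in females and at 34.6 and 88.2 CPM in males. UMIs of Fos were found in 11.9% of WT-CNO and 26.04% of DREADD-CNO OPC-like cells (median depths 10400.5 and 15102.5 UMIs), and in 10.3% and 10.9% of COP-like cells (30123 and 28981 UMIs). Fos was at 4.30 and 4.68 CPM in COP-like cells and at 4.62 and 3.90 CPM in OL-like cells, and Egr1 at 6.20 and 8.35 CPM in COP-like cells. In microglia-like cells Fos, Egr1 and Ier2 were far more abundant and higher in value, none of them past the rule. Fos was at 2159 and 2573 CPM (ratio 1.19), Egr1 at 889 and 1131 CPM (ratio 1.27) and Ier2 at 472 and 611 CPM (ratio 1.29). The immediate early list had a median of 0.22 (percentile 99.95) in these cells. In border macrophage-like cells this list was lower, at -0.099 (percentile 1.29), with Fos at 2096 and 1992 CPM (ratio 0.950, 0.907 to 0.996).

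**Figure D4:**
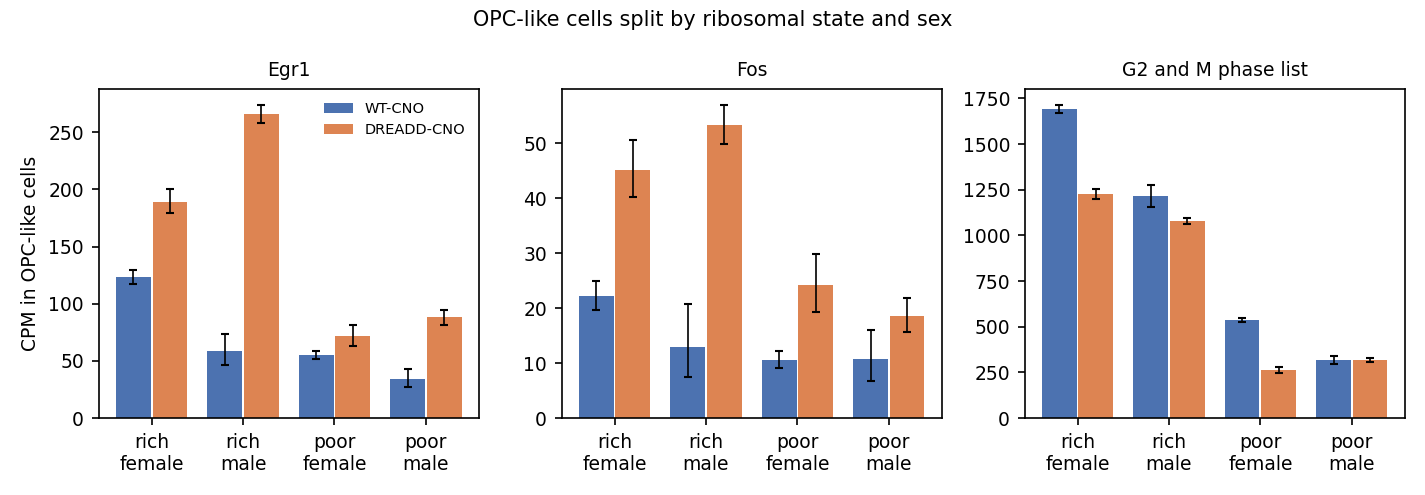
CPM of Egr1, Fos and the G2 and M phase list in OPC-like cells of each library, split by ribosomal state and sex; bars are CPM and lines are exact Poisson 95% intervals. Egr1 was higher in the DREADD-CNO library in all 4 groups of cells, while the G2 and M phase list was at 318 CPM in both libraries among ribosomal-poor male cells.

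Division of OPC-like cells was described from the G2 and M phase genes. The list had a median log2 ratio of -0.30 (percentile 0), with all 18 members lower in value. Among its members, Top2a, which untangles DNA in mitosis, was at 189 and 129 CPM (ratio 0.681), Kif11, a spindle motor gene, had 0.683, and Cenpf, a kinetochore gene, had 0.831. With each cell thinned to 5115 UMIs, which left out 325 and 282 shallower cells, 19.8% (18.2 to 21.5) of WT-CNO and 15.3% (13.8 to 16.9) of DREADD-CNO OPC-like cells held at least 2 of these UMIs. The difference was -4.52 points (-6.73 to -2.29), and without thinning the shares were 31.7% and 27.6%. In COP-like and OL-like cells, which have left the cycle, the thinned shares were 2.61% and 1.22%. Cells in clusters led by cell cycle genes were 17.2% and 15.5% of OPC-like cells, a difference of -1.73 points (-3.76 to 0.313). This difference was -1.25 points (-5.11 to 2.44) within ribosomal-rich cells and -3.76 points (-6.17 to -1.26) within ribosomal-poor cells. The thinned difference was -8.70 points within ribosomal-rich cells and -4.51 points within ribosomal-poor cells, and -3.76 and -6.73 points among female and male cells. The list medians by sex were smaller or of the other sign, at -0.060 (percentile 7.95) in female and 0.24 (percentile 98.2) in male OPC-like cells. The pooled median of -0.30 lay below both. It also takes in cells with both or neither sex signal, and the libraries differ in their mix of sexes. What each of these added to the pooled fall was not tested. In CPM the list was lower in female cells, at 1692 and 1227 in the ribosomal-rich state and 536 and 264 in the ribosomal-poor state. In males it was at 1215 and 1081 in the ribosomal-rich state and at 318 in both libraries in the ribosomal-poor state. Ribosomal-poor cells were 76.4% and 50.9% of male OPC-like cells, so the male median of 0.24 pools unlike mixes of the states. S phase genes had a median of -0.14 (percentile 0.370), with 15 of 18 members lower in value and ratios of 0.906 for Pclaf, 1.05 for Pcna, 0.783 for Clspn and 0.817 for Dtl. The thinned share of cells with S phase UMIs was 32.0% and 28.8% (difference -3.25 points, -5.93 to -0.550), against 15.7% and 15.9% in COP-like and OL-like cells, and without thinning it was 51.1% and 55.7%.

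The share of UMIs on myelin genes gave a measure of differentiation without clusters. It was 0.988% in WT-CNO and 1.26% in DREADD-CNO lineage cells (ratio 1.27, 1.27 to 1.28). The ratio was 1.01 within ribosomal-rich cells and 1.496 within ribosomal-poor cells. By class it was 1.32 in OPC-like, 1.17 in COP-like and 0.919 in OL-like cells. The OL-like ratio was 1.18 (1.16 to 1.20) in male and 1.07 (1.04 to 1.10) in ribosomal-poor cells, above 1, and 0.953 in female and 0.891 in ribosomal-rich cells. Free RNA was estimated from microglia-like cells, which do not express these genes. Mbp UMIs were found in 63.1% and 83.1% of OPC-like cells, and in 63.7% and 80.7% of microglia-like cells (median depths 17724 and 17653 UMIs). The Mbp difference was 63.9 CPM (58.8 to 69.1) in OPC-like and 78.8 CPM (65.1 to 92.9) in microglia-like cells, where the ratio was 2.07 in female and 3.04 in male cells. The OPC-like difference of Mbp was therefore no larger than that in microglia-like cells and may be background. In COP-like cells the Mbp difference was 274 CPM (247 to 302), beyond that in microglia-like cells. Ttr was found in 0.151% and 34.8% of OPC-like cells and in 0.601% and 37.3% of microglia-like cells. It was at 288916 CPM in the choroid-like cells of the DREADD-CNO library, so its level in lineage cells was read as background.

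Within COP-like cells, 7077 genes were measured, of which 9 were higher and 34 lower in the DREADD-CNO library by the rule. Within ribosomal-rich cells 8 were higher and 22 lower, and within ribosomal-poor cells 135 and 72. With the same mix of clusters the numbers were 10 and 13. The lower genes included Pdgfra, the growth factor receptor of precursors (41.2 and 21.3 CPM, ratio 0.517, 0.464 to 0.576), and Grm7, a metabotropic glutamate receptor gene (81.5 and 38.5 CPM, ratio 0.473, 0.437 to 0.511). Kcnd2, a potassium channel gene, was at 414 and 239 CPM (ratio 0.578, 0.559 to 0.597), and Nrxn3, a presynaptic adhesion gene, at 237 and 135 CPM (ratio 0.570). Tenm2 had a ratio of 0.450, the ubiquitin ligase gene March1 0.473, Tafa1 0.515, Gpr158 0.520, Caln1 0.556 and the phosphodiesterase gene Pde7b 0.562. The higher genes included Fbxo32, a ubiquitin ligase gene (14.1 and 24.5 CPM, ratio 1.73, 1.49 to 2.02), and Ttr, with 1 UMI in the WT-CNO library (ratio 449, 80.5 to 17771). All 10 named lower genes stayed at least 1.5 times lower within ribosomal-rich cells, and 6 did so with the same mix of clusters. With each library clustered on its own, Pdgfra, Gpr158 and Pde7b were higher in the DREADD-CNO library instead. Only 58 male COP-like cells were in the WT-CNO library, and 6 of the 10 were lower in both sexes. In microglia-like cells 9 of the 10 were lower in value too, and 3 of them (Pdgfra, Gpr158 and Pde7b) fell by at least as many CPM there as in COP-like cells, Pdgfra from 56.1 to 33.6 CPM. Kcnd2 fell from 176 to 71.7 CPM and Nrxn3 from 85.0 to 22.5 CPM in microglia-like cells, and March1 had a ratio of 0.502 in border macrophage-like cells. By sex, all 10 were lower in female microglia-like cells but only 3 in male ones, of which the WT-CNO library held 39. Kcnd2 had ratios of 0.511 and 1.76, Nrxn3 0.152 and 3.19, and Pdgfra 0.631 and 2.19 in female and male microglia-like cells, and March1 0.341 and 1.08 in border macrophage-like cells. Within the WT-CNO library, 186 female and 39 male microglia-like cells held 695 and 17 UMIs of Kcnd2 and 322 and 5 of Nrxn3. For Mbp they held 263 and 36, and March1 (402 and 54) and Tafa1 (18 and 3) lay closer to this. Free RNA should be shared by the cells of a library, so the microglia-like level may not measure free RNA alone. How much of these COP-like falls was free RNA was therefore left open.

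Of 24 lists measured in COP-like cells, 3 lay above and 11 below the central 95% of random lists. The myelin list (median 0.22, percentile 100) had all 11 members higher in value and 0 by the rule, with ratios of 1.18 for Cd9 and 1.34 for Gjc3. The cholesterol list (median 0.19, percentile 100) had 20 of 21 members higher in value and 1 by the rule, with ratios of 1.18 for Hmgcs1, 1.14 for Cyp51 and 1.41 for Insig1. Genes of committed and newly formed oligodendrocytes (median 0.063, percentile 97.9) had 9 of 12 members higher in value, with ratios of 1.01 for Bcas1, 1.02 for Fyn, 1.23 for Cnksr3 and 0.872 for Gpr17. The OPC identity list (median -0.25, percentile 0) had 7 of 10 members lower in value and 2 by the rule, Pdgfra and Cspg4 (ratio 0.659), with 0.811 for Lhfpl3 and 0.874 for Ptprz1. GABA receptor genes (median -0.29, percentile 0) were lower in value in 9 of 9 members, with ratios of 0.907 for Gabrg3 and 0.735 for Gabrg1. Voltage-gated channel genes (median -0.25, percentile 0) were lower in value in 12 of 16 and by the rule in 1, with 0.837 for Cacna1c and 0.723 for Kcnd3. Metabotropic glutamate receptor genes (median -0.32, percentile 0.300) were lower in value in 3 of 3, with 0.797 for Grm5. Synaptic adhesion genes (median -0.15, percentile 0.015) were lower in value in 13 of 17, with 0.883 for Nlgn1 and 0.898 for Dscam. AMPA receptor auxiliary genes (median -0.11, percentile 0.980) were lower in value in 5 of 8, with 1.03 for Cacng4, 0.743 for Grip1 and 0.874 for Cacng7.

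Trophic and modulator receptor genes had a COP-like median of -0.20 (percentile 0.010), with ratios of 0.906 for Erbb4, 1.34 for Lpar1 and 0.853 for P2rx7. Genes that inhibit differentiation had a median of -0.15 (percentile 0.290), with 0.879 for Sox6, 0.906 for Tcf4 and 0.825 for Sox5. BMP, Notch and Wnt targets had a median of -0.16 (percentile 1.69), with 0.754 for Id3 and 1.07 for Smad7. Cell cycle exit genes had a median of -0.15 (percentile 0.730), with 0.902 for Cdkn1c, 0.953 for Rb1, 0.832 for Ccnd1 and 0.884 for Ccnd3. Glycolysis genes had a median of -0.077 (percentile 0.590), with 0.923 for Gapdh, 0.954 for Ldha, 0.886 for Pfkp and 0.919 for Pfkl. The other 10 lists lay between -0.080 for AMPA receptor subunits and 0.16 for immediate early genes. In microglia-like cells OPC identity genes had a median of -0.62, voltage-gated channels -0.52, AMPA receptor auxiliary genes -0.49, synaptic adhesion genes -0.42, trophic receptors -0.29, myelin genes 0.58 and genes of committed and newly formed oligodendrocytes 0.17 (percentile 98.0), the same directions as in COP-like cells. Cholesterol synthesis (-0.019) and cell cycle exit genes (0.15) had the other direction in microglia-like cells. In border macrophage-like cells both had the COP-like direction, cholesterol synthesis at 0.23 (percentile 98.7) and cell cycle exit genes at -0.079 (percentile 31.9). With the same mix of clusters, 3 of the 3 higher and 3 of the 11 lower lists stayed outside on the same side, and within ribosomal-rich cells 3 and 9 did. In ribosomal-poor cells 1 and 5 did so, in female cells 1 and 8, and in male cells 2 and 2.

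Within OL-like cells, 6581 genes were measured, of which 19 were higher and 51 lower in the DREADD-CNO library. The late myelin genes Mal and Opalin were among the higher, at 20.8 and 68.3 CPM for Mal (ratio 3.28, 2.76 to 3.90) and 9.37 and 24.2 CPM for Opalin (ratio 2.59, 2.00 to 3.39). Mal UMIs came from 11 cells in each library, with 93.7% and 98.5% of them in the 5 richest cells, and Opalin UMIs from 9 and 27 cells, with 94.4% and 81.7% of them in the 5 richest, so both values rest on few mature cells. Pde1c, a phosphodiesterase gene, had a ratio of 1.75, Gpr146 and Ppp1r14a had 1.61 each, and Rgmb, a BMP co-receptor gene, had 1.61. Flot1, Synpr and the proline synthesis gene Pycr1 had ratios of 1.57, 1.56 and 1.56, and Ttr, with 1 UMI in the WT-CNO library, had 201 (35.8 to 7953). Lower genes included the RNA splicing regulator Rbfox1 (37.6 and 11.1 CPM, ratio 0.295, 0.241 to 0.362), the sarcoglycan genes Sgcd and Sgcz (ratios 0.309 and 0.354), and the ion channel gene Asic2 (ratio 0.360). Tenm2 had a ratio of 0.390, Il23a 0.397, the channel modulator Fgf14 0.410, March1 0.451, the adhesion gene Pcdh15 0.479 and the GABA receptor gene Gabrb1 0.498. All 10 lower genes stayed at least 1.5 times lower within ribosomal-rich cells and with the same mix of clusters, and 8 were lower in both sexes. In microglia-like cells 7 of these 10 fell by at least as many CPM as in OL-like cells, among them Rbfox1 (93.9 to 43.4 CPM), Asic2 (50.7 to 11.9), Sgcz (65.5 to 22.5), Pcdh15 (142 to 54.0) and Fgf14 (71.6 to 27.8), with both sexes pooled. By sex, 9 of the 10 were lower in female microglia-like cells and 2 in male ones. The ratios in female and male cells were 0.337 and 3.22 for Asic2, 0.305 and 3.56 for Sgcz, 0.350 and 1.46 for Pcdh15, and 0.350 and 1.27 for Fgf14, with 2 to 16 UMIs of each in the 39 male WT-CNO cells. Female WT-CNO microglia-like cells held 237 UMIs of Asic2, 233 of Sgcz, 571 of Pcdh15 and 279 of Fgf14. Such a gap between the sexes of a library means that the microglia-like level may not measure free RNA alone. How much of the OL-like falls was free RNA was left open. The other 3 of the 10 were Tenm2, Il23a and Gabrb1. Of the 10 higher genes, 9 kept a ratio of at least 1.5 within ribosomal-rich cells and 5 with the same mix of clusters, where the others included Gpr146 at 1.28, Rgmb at 1.33, Flot1 at 1.36 and Pycr1 at 1.31, and 6 were higher in both sexes. With thinning before clustering, Flot1 and Rgmb were lower in the DREADD-CNO library instead. The WT-CNO library held 227 OL-like cells, 19 of them male.

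Of 24 lists measured in OL-like cells, 2 lay above and 8 below the central 95% of random lists. Cholesterol synthesis (median 0.14, percentile 99.99) had 20 of 21 members higher in value and 0 by the rule, with ratios of 1.05 for Hmgcs1 and 1.24 for Hsd17b7. Glycolysis (median 0.12, percentile 99.3) had 12 of 14 members higher in value, with 1.07 for Gapdh, 1.27 for Ldha and 0.809 for Pfkp. OPC identity (median -0.25, percentile 0.015) had 2 of 9 members lower by the rule, Pdgfra (ratio 0.512) and Cspg5 (0.626), with 0.872 for Ptprz1 and 1.03 for Sox2. Voltage-gated channels (median -0.22, percentile 0.070) had 12 of 13 members lower in value and 2 by the rule, Kcnd2 (ratio 0.604) and Cacna1c (0.665), with 0.942 for Kcnj10. GABA receptor genes (median -0.31, percentile 1.52) were lower in value in 5 of 5, with 0.994 for Gabbr1. Metabotropic glutamate receptor genes (median -0.23, percentile 1.59) had 0.752 for Grm7 and 0.852 for Grm5, and AMPA receptor auxiliary genes (median -0.18, percentile 1.56) had 0.812 for Shisa9, 0.834 for Grip1 and 0.740 for Shisa6. Trophic receptor genes (median -0.16, percentile 0.910) had 0.849 for Erbb4, 0.993 for Gpr17 and 0.728 for Ntrk2. Immediate early genes (median -0.29, percentile 0.930) had 0.803 for Jund and 0.814 for Jun, opposite in direction to OPC-like cells. Lipid synthesis genes (median -0.062, percentile 1.96) had 0.958 for Scd2, 1.04 for Acsl3, 0.814 for Elovl6 and 0.876 for Elovl7. The myelin list, at -0.047 (percentile 3.88), was among the other 14 lists, which lay between -0.19 for interferon response and 0.067 for AMPA receptor subunits. The lower lists of OPC identity, voltage-gated channel, AMPA receptor auxiliary and trophic receptor genes were lower in microglia-like cells as well, at -0.62, -0.52, -0.49 and -0.29. Of the 2 higher and 8 lower lists, 1 and 7 stayed outside on the same side with the same mix of clusters, 1 and 5 within ribosomal-rich cells, 1 and 1 within ribosomal-poor cells, 1 and 3 in female cells, and 2 and 1 in male cells.

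Across all lineage cells, where the classes are mixed, 18 of 7659 genes were higher and 91 lower in the DREADD-CNO library. Dynll2, a motor light chain gene, was at 419 and 661 CPM (ratio 1.58), and the G protein subunit gene Gng4 had a ratio of 1.74. Gp1bb had 1.69, the adhesion gene Epcam 1.64, Mycl 1.54, Tex14 1.54, the kinase gene Pak4 1.53, Fos 1.93, Egr1 1.83 and Ttr 98.6. Among the lower genes were Tenm2 (252 and 120 CPM, ratio 0.476), the mitotic genes Top2a (0.539), Kif11 (0.550), Mki67 (0.564) and Cenpe (0.566), and Kctd16 (0.529), a partner of GABA-B receptors. Ebf1 had 0.539, Sncaip 0.551, the adhesion gene Cntnap2 0.563 and the calcium channel gene Cacnb2 0.568. Matching the mix of clusters left 9 genes higher and 6 lower, of which 8 and 6 were among the 18 and 91.

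The last question, from the study's title, concerned AMPA receptors, which carry fast glutamate signals to OPCs. In OPC-like cells all 4 subunit genes were lower in value and none passed the rule. Gria1 (ENSMUSG00000020524) was at 132 and 118 CPM, Gria2 (ENSMUSG00000033981) at 1250.0 and 1201 CPM, Gria3 (ENSMUSG00000001986) at 574 and 554 CPM and Gria4 (ENSMUSG00000025892) at 745 and 658 CPM. The OPC-like ratios were 0.897, 0.961, 0.965 and 0.883. Matching the mix of clusters gave 0.994, 1.03, 1.02 and 1.02. By sex, Gria2 had a ratio of 1.03 (1.01 to 1.05) in female and 0.817 (0.793 to 0.842) in male OPC-like cells. Gria1 had 0.834 and 0.871, Gria3 1.00 and 0.877, and Gria4 0.810 (0.787 to 0.834) and 0.919 (0.881 to 0.958) in female and male cells. In COP-like cells Gria1 was at 11.7 and 5.13 CPM (ratio 0.437, 0.352 to 0.542), under the minimum level of the rule, and in male cells, with 7 and 94 UMIs, its ratio was 1.19 (0.554 to 3.03), while Gria2, Gria3 and Gria4 had ratios of 1.01, 0.955 and 0.937. In OL-like cells Gria1 had 41 and 12 UMIs (ratio 0.166, 0.0797 to 0.323), with 34 and 2 in female cells and 0 and 8 in male cells. Gria2 was at 375 and 440 CPM in OL-like cells (ratio 1.17, 1.12 to 1.23), with 0.908 for Gria3 and 1.05 for Gria4. In microglia-like cells the AMPA receptor subunit list had a median of -0.70, with 3 of 3 measured members lower in value and 2 by the rule. Gria2, whose product limits calcium entry, made up 46.3% and 47.5% of AMPA subunit UMIs in OPC-like cells, a difference of 1.17 points (0.718 to 1.61). It was 0.307 points (-0.213 to 0.827) with the same mix of clusters, 3.67 points in female cells and -2.34 points in male cells. In COP-like cells the share was 37.1% and 38.9%, a difference of 1.75 points (1.02 to 2.48), which was 3.44 points (2.58 to 4.30) with the same mix of clusters, 3.02 points in female cells and 0.0244 points (-1.83 to 1.85) in male cells. In OL-like cells it was 40.8% and 44.0%, a difference of 3.21 points (1.78 to 4.64), 2.25 points (0.612 to 3.89) with the same mix of clusters, 4.49 points (1.93 to 7.06) in female cells and 1.80 points (-2.49 to 5.98) in male cells.

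**Figure D5:**
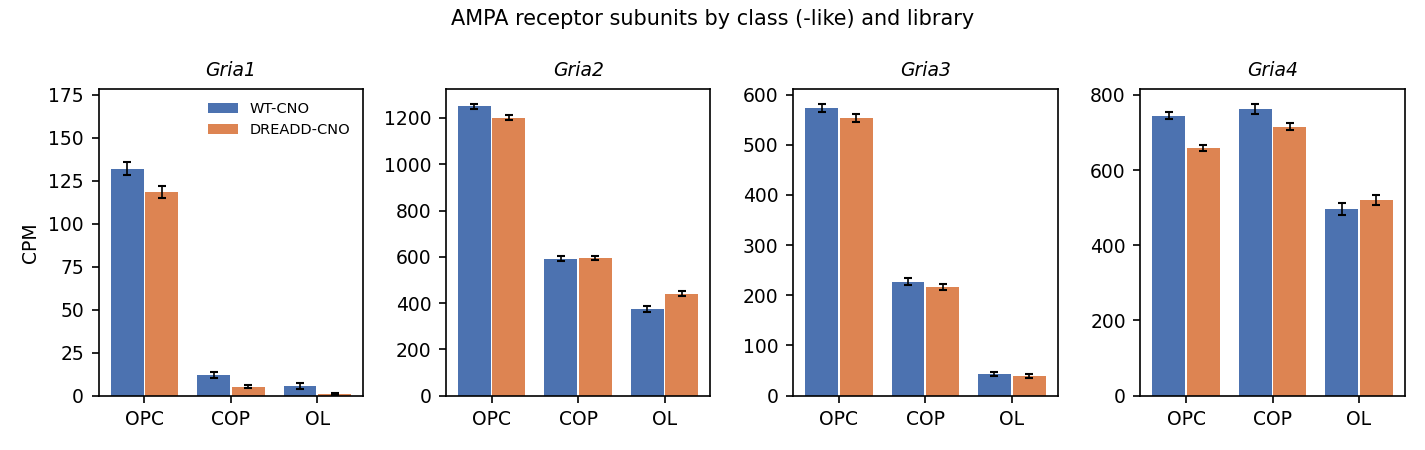
CPM of the AMPA receptor subunit genes Gria1, Gria2, Gria3 and Gria4 in OPC-like, COP-like and OL-like cells of each library; bars are CPM and lines are exact Poisson 95% intervals. Gria2 was at 1250.0 and 1201 CPM in OPC-like cells and at 375 and 440 CPM in OL-like cells.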

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

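All tests in this part were chosen after the result was seen, except the test of cell depth. The genes named by rank in each lineage class and the Gria2 shares were compared by sex. In 3 of these results the counting intervals of female and male cells lay on opposite sides. The difference between the sexes was not tested in any of them. Other results also turned by sex, among them the OL-like myelin share ratio (0.953 and 1.18) and the OPC-like Gria2 ratio (1.03 and 0.817). Tenm2 in COP-like cells had a DREADD-CNO over WT-CNO ratio of 0.491 in female cells and 2.66 in male cells, where the WT-CNO value rests on 12 UMIs in 58 cells. Mal in OL-like cells had a ratio of 0.0582 in female cells, with 2 UMIs in the DREADD-CNO library, and 24.5 in male cells, with 2 UMIs in the WT-CNO library. The Gria2 share of AMPA subunit UMIs in OPC-like cells differed by 3.67 points in female cells and by -2.34 points in male cells.

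The OPC-like share was lower in the DREADD-CNO library by -14.9 points. The share of ribosomal-poor cells, which differed between the libraries, was argued against as the whole cause by a difference of -9.14 points (-11.4 to -6.92) within ribosomal-poor cells. The rule for this test, unlike that for the cycling result below, let either state alone argue against the cause. Within ribosomal-rich cells the OPC-like difference was -2.95 points (-6.36 to 0.479), with an interval on both sides of no difference. The COP-like difference there was 4.42 points (1.12 to 7.65). The sex makeup of the pools was argued against by differences of -12.9 points in female and -16.4 points in male cells. Cell depth was argued against by a difference of -14.6 points after thinning every cell. Silencing of neurons, the genotype, differences between the few pooled pups, and the dissociation and bead selection of each library stay open. They were not tested apart. The captures differed outside the lineage, with 3 and 84 endothelial-like, 3 and 35 astrocyte-like and 333 and 233 microglia-like cells in the WT-CNO and DREADD-CNO libraries.

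Mbp had more UMIs in OPC-like cells of the DREADD-CNO library. Free RNA may account for this, since the difference was 78.8 CPM in microglia-like cells, which do not make myelin. Expression of myelin genes by OPC-like cells as the whole cause was argued against by a smaller difference of 63.9 CPM in OPC-like cells. The source of the free RNA was not tested.

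Fewer OPC-like cells of the DREADD-CNO library held G2 and M phase UMIs. The share of ribosomal-poor cells as the whole cause was argued against by the thinned difference within the state with the smaller difference, -4.51 points (-7.19 to -1.72). The sex makeup of the pools as the whole cause was argued against by thinned differences of -3.76 points (-7.06 to -0.108) in female and -6.73 points (-12.6 to -1.63) in male cells at the planned minimum of 2 UMIs. The margin is narrow, since with at least 3 UMIs the differences were -2.58 points (-5.49 to 0.718) and -0.539 points (-5.56 to 3.50). Without thinning the male interval included 0 (-11.6 to 0.281), and the list medians were -0.060 (percentile 7.95) in female and 0.24 (percentile 98.2) in male cells. By cluster, cells in clusters led by cell cycle genes differed by -1.73 points (-3.76 to 0.313), an interval that includes 0. The difference was -1.25 points (-5.11 to 2.44) within ribosomal-rich cells and -3.76 points (-6.17 to -1.26) within ribosomal-poor cells. Silencing of neurons stays open and was not tested apart from the genotype, the pups and the library.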

How the results depend on the processing

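The alternatives by sex for lists, cycling, myelin share and Gria2 share, those by ribosomal state, the 20% mitochondrial limit, and those without clusters 3 and 22 or cluster 9 were chosen after seeing the data. No paired analysis was possible because each group was 1 pool. Over 21 settings, gene counts stayed within 1.5 times in 48 of 80 alternatives. For named genes, 1080 of 1513 alternatives stayed within the counting interval, 425 moved and 8 reversed. Only genes past the rule could count as reversed, so a turn of direction in Gria1 to Gria4 counted as moved. Of the set of genes named by rank, the number still named stayed within 1.5 times in 38 of 80 alternatives and not in 42. For lists 353 of 427 did so, 62 moved and 12 reversed, and for shares 46 of 77 did so, 28 moved and 3 reversed. Female OL-like, male COP-like, male OL-like and ribosomal-poor OL-like cells had fewer than 100 cells in a library and entered neither the gene counts nor the named genes here, and values given for them rest on few cells. The cause was not tested unless stated.

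For the OPC-like share, DREADD-CNO minus WT-CNO, points of difference were -18.5 with each library clustered on its own, -9.70 with a 5% mitochondrial limit, -2.95 and -9.14 within ribosomal-rich and ribosomal-poor cells, and -17.1 without clusters 3 and 22. For the COP-like share, DREADD-CNO minus WT-CNO, points were 17.5 with separate clustering, 7.51 with the 5% limit, 4.42 and 7.29 within ribosomal-rich and ribosomal-poor cells, 7.84 at resolution 0.5 and 8.84 with classes from the markers of each cell. For the OL-like share, DREADD-CNO minus WT-CNO, points were 0.956 with separate clustering, -1.47 within ribosomal-rich cells, 6.68 at resolution 0.5, 6.17 with markers of each cell, 4.09 with a minimum of 1000 genes, 4.22 with a 20% mitochondrial limit and 1.09 in female cells.

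Of genes past the rule of size, OPC-like cells held 68. They held 1017 with no minimum, 37 at a CPM of at least 50, 11 at a ratio of at least 2, 21 with the same mix of clusters, 181 with thinning, 541 in male cells and 240.0 without clusters 3 and 22. Of genes past the rule of size, COP-like cells held 43, and under the same first 5 settings 780.0, 22, 10, 23 and 113. They held 20 with a minimum of 1000 genes, 24 with no doublet removal, 79 with separate clustering, 207 within ribosomal-poor cells and 17 with a 20% mitochondrial limit. Of genes past the rule of size, OL-like cells held 70, with 753 without a minimum, 27 at a CPM of at least 50, 19 at a ratio of at least 2, 46 with thinning, 123 with a 5% mitochondrial limit, 46 with no doublet removal and 202 with separate clustering. Of genes past the rule of size, all lineage cells held 109, and under the first 5 settings 1350.0, 37, 10, 15 and 270.0. They held 47 with a 5% mitochondrial limit, 352 in male cells and 41 within ribosomal-rich cells. Stricter or looser minimums change these counts by construction.

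The immediate early median in OPC-like cells was 0.42 at a mean CPM of at least 20, 0.32 with the same mix of clusters, 0.46 and 0.40 within ribosomal-rich and ribosomal-poor cells, and 0.44 and 1.23 in female and male cells. The G2 and M phase median in OPC-like cells was -0.48 with the same mix, -0.66 and -0.72 within ribosomal-rich and ribosomal-poor cells, and -0.060 and 0.24 in female and male cells. Cholesterol synthesis in OPC-like cells was at 0.16 with the same mix and 0.16 within ribosomal-rich cells, and OPC identity in COP-like cells at -0.14 with the same mix. Medians on the other side were, for BMP, Notch and Wnt targets in OPC-like cells, -0.084 with the same mix, -0.0036 within ribosomal-rich and -0.13 within ribosomal-poor cells, and in COP-like female cells 0.0075. Glycolysis was at -0.030 in ribosomal-rich OPC-like and 0.027 in ribosomal-poor COP-like cells. GABA receptors in COP-like cells were at 0.0041 and lipid synthesis in OL-like cells at 0.021 with the same mix. In ribosomal-poor OL-like cells lipid synthesis was at 0.0054, cholesterol synthesis at -0.012 and metabotropic glutamate receptors at 0.40.

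Named genes reversed in log2 ratio with separate clustering in COP-like cells (Gpr158 0.075, Pde7b 0.18, Pdgfra 0.33) and with thinning in OL-like cells (Flot1 -0.45, Rgmb -0.49). Ror2 was at 0.033 in male OPC-like cells, Kctd16 at 0.13 in male lineage cells and Fbxo32 at -0.13 in ribosomal-poor COP-like cells. The thinned G2 and M phase difference was -8.70 points in ribosomal-rich cells, and the S phase difference 4.60 points without thinning. The myelin share ratio was 1.11 at a 5% mitochondrial limit, 1.01 and 1.496 in ribosomal-rich and ribosomal-poor cells, and 1.24 and 1.61 in female and male cells. The Gria2 share difference was 2.18, 3.67 and -2.34 points in ribosomal-rich, female and male OPC-like cells, 3.22 and 3.02 points with thinning and in female cells for COP-like cells, and 5.82 points with thinning for OL-like cells.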

Other observations

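The test of the chromosome segment and all comparisons in this part were chosen after the values were seen, as were the genes named in it. Microglia-like cells, 333 and 233 in the WT-CNO and DREADD-CNO libraries, had 186 genes higher and 206 lower of 6403 measured. The inflammatory genes Tnf (26.03 and 80.04 CPM, ratio 3.07, 2.52 to 3.76), Dusp2 (ratio 3.02) and Nfkbia (144 and 373 CPM, ratio 2.59, 2.37 to 2.82) were higher in the DREADD-CNO library, and each was so in female and in male cells. The G2 and M phase list had all 18 members higher by the rule (median log2 ratio 1.12, percentile 100), with Mki67 at 95.8 and 213 CPM and Top2a at 107 and 246 CPM. Thinned to 5115 UMIs, which left out 90 and 65 cells, 30.5% and 44.0% of microglia-like cells held at least 2 of these UMIs, a difference of 13.6 points (4.12 to 22.9). It was 0.115 points in female and 12.3 points (-6.39 to 28.8) in male cells. Without thinning the shares were 60.7% and 63.9%, a difference of 3.29 points (-4.85 to 11.2), and -3.16 points in female cells. Lower genes included Gdf15, a stress cytokine gene (44.8 and 3.28 CPM, ratio 0.0733), Atp6v0d2, a lysosomal pump gene (ratio 0.321), and the chemokine genes Ccl4 and Ccl3 (ratios 0.531 and 0.656). The lipid carrier gene Apoe had a ratio of 0.682, short of the rule. Microglia-like OPC identity genes had a median of -0.62.

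Border macrophage-like cells, 128 and 174, had 39 genes higher and 58 lower of 3421 measured. Nr4a3, an immediate early nuclear receptor gene (77.4 and 14.7 CPM, ratio 0.190), and Tnfsf18, a cytokine gene (186 and 79.5 CPM, ratio 0.428), were lower in the DREADD-CNO library. Tnfsf18 had ratios of 0.371 in female and 1.70 in male cells, on opposite sides, and Nr4a3 0.231 and 0.164. Ifi27l2a, an interferon-induced gene (190 and 356 CPM, ratio 1.87, with 1.17 in female and 1.37 in male cells), was higher, as was Ccl4 (ratio 1.89), which had ratios of 0.619 in female and 3.02 in male cells. The G2 and M phase list had 15 of 15 members higher in value (median log2 ratio 1.36, percentile 100) and 0 by the rule.

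Chn2, a Rac regulator gene, was at 556 and 741 CPM in COP-like cells (ratio 1.33), and its neighbour 9130019P16Rik at 27.1 and 50.2 CPM (ratio 1.85). In OPC-like cells Chn2 had a ratio of 0.998. Between gene midpoints, both lie within 1.51 Mb of Neurod6 on chromosome 6 (GRCm38, Chn2 at 54039554 to 54301810 and Neurod6 at 55677822 to 55681263). 9130019P16Rik was also among the 10 leading genes of COP-like cluster 23, which held 106 WT-CNO and 289 DREADD-CNO cells. The mix of clusters was not tested as a cause for either gene. One hypothesis is that a segment that came with the Cre allele may carry regulatory variants. The 49 expressed genes within 15 Mb of Neurod6 had a median absolute log2 ratio of 0.084 in COP-like cells, at percentile 54.0 of 5689 windows of equally many genes (median 0.083). The test neither showed a shift of the segment nor excluded an effect on single genes, so the hypothesis stays open.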
